A study of Xenopus laevis with 4 samples.

How the data were processed

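RNA-seq libraries were made from total RNA with a directional kit, per the labels' protocols, from pools of 3 posterior explants each, 2 pools treated with 0.5 mM picrotoxin for 3 h and 2 control pools. The authors deposited 1 table of estimated counts per RefSeq transcript, not scaled, with 80178 transcripts and 1 column per library. The aligner, the quantification tool and the genome build are not given in the sources used here. The values are not all whole numbers (between 44.5% and 46.9% of the transcripts lie within 0.001 of one), so they were treated as estimated counts. Every transcript was matched by its versioned identifier to the RefSeq annotation of Xenopus_laevis_v10.1, transcripts were summed to 39176 genes, and sums were rounded to whole counts. That annotation was used for gene names and for which genes share a chromosome and neighbour each other, and no coordinates are printed. Of the genes, 35819 had at least 1 count. There were 48 ribosomal RNA gene models, kept in the library totals, and no mitochondrially encoded gene model, so that planned list was not run.

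The design planned raw gene counts, and the rounded sums took their place. Genes were filtered with filterByExpr, libraries scaled with TMM, and the groups compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust = TRUE, after estimateDisp) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over 26752 genes and a threshold of 0.05. The biological coefficient of variation was 8.80%. The 2 libraries of a group were separate pools, per the labels. Whether the pools came from different clutches is not given, so the p-values of single genes measure the spread between pools. Library totals of 18164631 to 20974160 counts, and 11258577 to 15707090 outside ribosomal RNA, set the depth. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 3.56 to 5.32), so no library was counted as a repeat. CPM values are TMM scaled. Standard errors of log2 fold changes were derived from the F statistic.

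Gene lists were tested with camera from limma 3.58.1 (preset correlation 0.01), over 41 lists with at least 5 tested members, and again with an estimated correlation and with fry. The 39 lists of the design and the lists of ribosomal protein and histone genes, found by symbol, were fixed before the data were examined. L and S copies counted as separate members, although their log2 fold changes correlated at 0.47 over 4015 pairs (Pearson). A synonym that matched ttn to another gene was dropped, 1 match in all. The lists are immediate early genes, GABA-A and glycine receptor subunits, GABA and glycine synthesis, glutamate receptors, cholinergic genes, voltage-gated channels, neuron differentiation, neural progenitors and spinal neuron subtype factors. They cover neural crest and pigment cells, skeletal muscle, notochord, tailbud, posterior and anterior Hox genes, epidermis, multiciliated cells, endoderm, blood, myeloid cells, pronephros, limb and heart. They also cover heat shock, ER stress, p53 targets, hypoxia, xenobiotic metabolism, Notch, FGF, Wnt, Hedgehog, BMP and retinoic acid genes, cell cycle, extracellular matrix, calcium handling, neuropeptides, sterol synthesis and the circadian clock. For the limb and the blood list the median was above 0 and the mean and the test below, and for the lists of calcium handling, voltage-gated channels and hypoxia the mean was below 0 and the median and the test above.

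Named genes followed a rule set before the data were examined. It took up to 10 higher and 10 lower genes with the largest change among called genes with a mean of at least 5 CPM, both picrotoxin libraries beyond both control libraries and a real symbol. It also took up to 4 members of each list with the smallest p (up to 6 where more were called), and fos, fosb, jun, junb, egr1, npas4, nr4a1, bdnf, arc and the detected GABA-A subunits whatever their value. The text names 7 genes from outside the rule, col1a1.L, col3a1.L, col6a1.L, col6a2.L, col5a2.L, krt12.5.L and LOC108715916, and does not name every gene the rule allows. One gene the rule took is not reported here.

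The tests were checked on simulated counts of 26466 to 26670 genes with the means and library sizes of picrotoxin against control and 200 changed genes, 4 draws for each kind of spread. With the spread on the fitted trend, 97 to 100 of 100 genes changed 2-fold and 59 to 67 of 100 changed 1.5-fold were called, beside 2 to 14 unchanged genes. With each gene at its own estimated spread, 96 to 98 and 54 to 62 were called, beside 26 to 43 unchanged genes, so that false calls then exceeded the nominal rate. In these draws genes were independent and no chromosome was offset. A neural progenitor list moved by log2 -0.25 was called by camera with the preset correlation and missed with an estimated correlation and by fry (26535 genes). Camera with the preset correlation called 2 of the 41 lists there, the second being Notch genes, a list that shares members with the moved one. This list check was 1 draw on the fitted trend, with genes drawn independently. It therefore cannot show how often camera calls unchanged lists whose members correlate. A chromosome 4S offset of -0.16 in control replicate 1 came back as -0.15, with other chromosomes within 0.02 (15993 genes).

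Alternatives planned before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, other filters on low counts, robust = FALSE, the replicate number as a block, L and S copies summed, and each library left out. Alternatives added after the data were seen removed ribosomal RNA gene models, set legacy = FALSE, or took out each library's chromosome medians, per chromosome or as a running median over 101 genes. Chromosome offsets were computed on 16021 genes of at least 5 CPM, as log2 CPM (prior count 2) of a library minus the mean of the others, less the library's median gene, with 1000 bootstrap draws for 95% intervals and 1000 shuffles of chromosome labels. Figures were drawn with matplotlib 3.10.9.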

Results

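RNA was sequenced from posterior explants of *Xenopus laevis* tailbud embryos at stage 26, cut behind the otic vesicle, kept for 3 h with or without 0.5 mM picrotoxin and then freed of ventral yolk. Picrotoxin blocks the chloride channel of GABA-A receptors. Each group had 2 libraries, and each library was a pool of explants from 3 embryos. The libraries held 18164631 and 20660589 estimated counts in control replicates 1 and 2. They held 20285273 and 20974160 in picrotoxin replicates 1 and 2. Ribosomal RNA gene models took 38.0%, 39.6% and 42.0% of the counts in control replicate 1, control replicate 2 and picrotoxin replicate 1, but 25.1% in picrotoxin replicate 2. That left 11258577, 12472531, 11759854 and 15707090 counts for other genes in the same order. *Xenopus laevis* is allotetraploid, and the L and S copies (homeologs) of a gene were kept as separate gene models.

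The comparison of picrotoxin with control asked which transcripts differed after 3 h of the drug. The radial glia fatty acid binding protein gene fabp7.L fell from 13.2 ± 1.30 to 5.92 ± 0.97 CPM (SD, n = 2 per group), a log2 fold change of -1.16 ± 0.16 (SE; adjusted p = 0.000532, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The activity-regulated transcription factor gene egr1.L fell from 10.2 ± 1.31 to 4.57 ± 1.41 CPM, a log2 fold change of -1.13 ± 0.19 (adjusted p = 0.0110). The clock repressor gene nr1d1.L rose from 3.53 ± 0.07 to 8.73 ± 0.69 CPM, a log2 fold change of 1.30 ± 0.18 (adjusted p = 0.000587). The keratin gene krt12.5.S rose from 679 ± 50.0 to 1184 ± 64.4 CPM, a log2 fold change of 0.80 ± 0.11 (adjusted p = 0.000593). The S copies of 5 collagen genes rose with log2 fold changes of 0.53 to 0.79. In all, 47 of the 26752 genes tested passed an adjusted p of 0.05, 22 higher and 25 lower with picrotoxin, and 2008 had an unadjusted p under 0.05. Some called genes near the count floor, not named here, moved further than those above. The farthest fell from 1.25 and 0.91 CPM in control replicates 1 and 2 to 0 in both picrotoxin libraries (log2 fold change -7.44, without a usable SE).

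**Figure D1:**
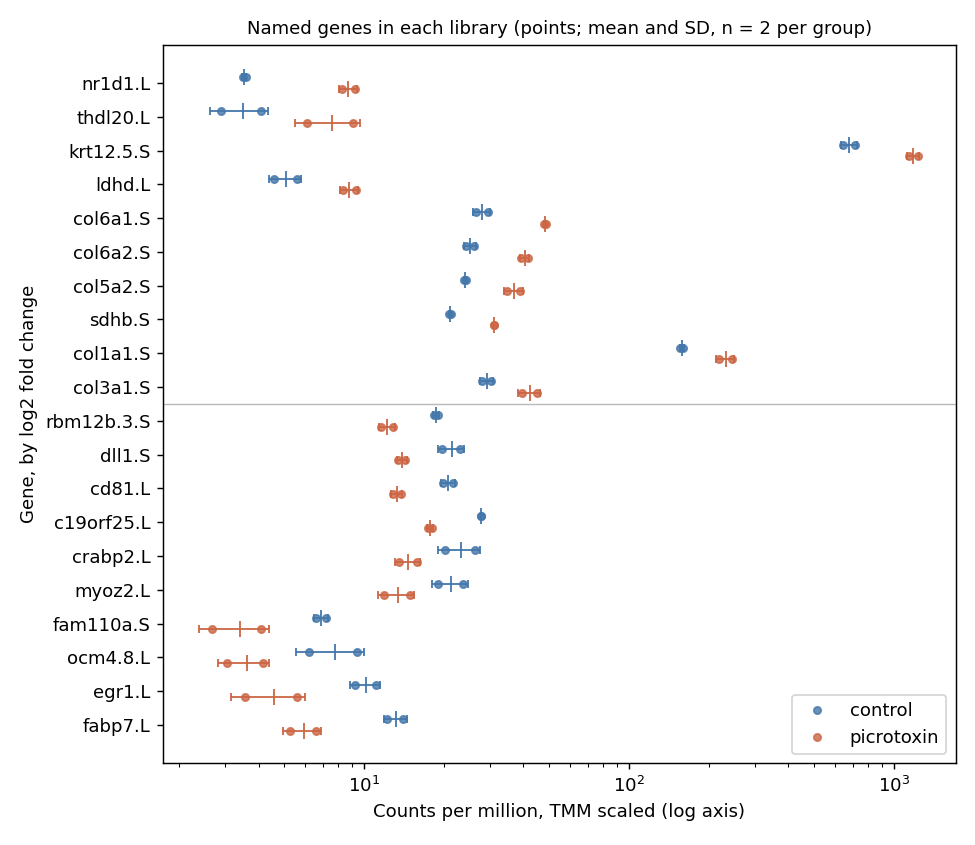
CPM on a log axis for the 10 higher and 10 lower genes with the largest changes among called genes with a mean of at least 5 CPM and a real symbol. Points are single libraries, ticks and bars are the mean and SD of the 2 libraries of a group, and for each gene both picrotoxin libraries lie beyond both control libraries, as the choice of genes required.

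The other named genes that rose were thdl20.L (log2 fold change 1.12), the D-lactate dehydrogenase gene ldhd.L (0.80) and the succinate dehydrogenase subunit gene sdhb.S (0.55). Those that fell were the parvalbumin family gene ocm4.8.L (-1.12), fam110a.S (-1.05), the muscle Z-disc gene myoz2.L (-0.68), the retinoic acid binding protein gene crabp2.L (-0.65), c19orf25.L (-0.64), the tetraspanin gene cd81.L (-0.64), the Notch ligand gene dll1.S (-0.63) and rbm12b.3.S (-0.61). The smallest p belonged to LOC108715916, named here after its values were seen, which rose from 9.52 ± 0.37 to 36.6 ± 3.56 CPM (log2 fold change 1.94 ± 0.12, adjusted p = 1.0e-09). Of the 22 called genes named here, 8 kept their call without control replicate 1, 3 without control replicate 2, 15 without picrotoxin replicate 1 and 16 without picrotoxin replicate 2. Only fabp7.L, col6a1.S and LOC108715916 kept it in all 4 of these fits. The whole count was 15 without control replicate 2, 131 without picrotoxin replicate 1 and 158 without picrotoxin replicate 2. With counts simulated for these libraries with no change, 0 genes passed when the spread followed the fitted trend, but 5 to 17 passed when each gene had its own estimated spread. The simulated genes were drawn independently, without the chromosome offsets of these libraries described below. These counts therefore do not give the number of false calls among the 47.

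Neural progenitor genes were lower as a group. Of the 71 gene models tested, fabp7.L fell, 0 rose and 70 did not pass, and 9 fell when adjusted over the list alone. Among them were the intermediate filament gene nes.L (log2 fold change -0.52), the neural transcription factor genes sox2.L (-0.60) and sox3.L (-0.54) and the glial glutamate transporter gene slc1a3.S (-0.38). The log2 fold change was negative for 55 of the 71, with a median of -0.24 (camera adjusted p = 1.5e-08 over 41 lists; adjusted p = 0.409 with an estimated correlation). With its preset correlation, camera sets the members of a list against the other genes. Its p, here and for the lists below, thus does not measure the spread between pools. With an estimated correlation, camera has only the 2 residual degrees of freedom of the 4 libraries. In 1 draw it then missed a simulated list moved by log2 -0.25. A call lost there, here and below, therefore does not show that a list did not move. The neural progenitor list alone passed fry, which asks whether its genes moved on balance one way (adjusted p = 0.0388). Notch pathway genes were lower too, with a median of -0.12 over 51 gene models (camera adjusted p = 0.000702; adjusted p = 0.409 with an estimated correlation). There dll1.S fell, 50 did not pass, and 4 fell adjusted over the list alone, including dll1.L (-0.41) and the Notch effector gene hes5.1.L (-0.52). The Notch list shares 24 of its 51 gene models with the neural progenitor list, and the other 27, tested after the lists were called, had a median of -0.07 and did not pass (camera adjusted p = 0.0962).

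Lists of later neural genes lay on the same side, with no member past the threshold over all genes. Spinal neuron subtype factors had a median of -0.19 over 59 gene models (camera adjusted p = 0.000608; adjusted p = 0.422 with an estimated correlation), with 0 adjusted over the list alone and isl1.S at -0.72. Neuron differentiation and structure genes had a median of -0.11 over 78 (camera adjusted p = 0.000702; adjusted p = 0.642 with an estimated correlation), and 2 fell adjusted over the list alone. These were the tubulin gene tubb2b.L (-0.42) and the RNA-binding protein gene elavl3.L (-0.48). The neuronal factor gene myt1.L was at -0.39. The mean log2 level of this neuron list, relative to the mean of all libraries, was 0.11 and 0.01 in the control libraries, 0.05 in picrotoxin replicate 1 and -0.17 in picrotoxin replicate 2, the library with the low ribosomal RNA share. Its call was lost without picrotoxin replicate 2 (adjusted p = 0.901) and without control replicate 1 (adjusted p = 0.112). Glutamate receptor and transport genes had a median of -0.15 over 26 gene models (camera adjusted p = 0.0470; adjusted p = 0.642 with an estimated correlation), with slc1a3.S alone falling adjusted over the list alone. The call on these genes was lost without control replicate 1 (adjusted p = 0.0739), control replicate 2 (adjusted p = 0.0919) or picrotoxin replicate 2 (adjusted p = 0.936). It was also lost with no filter on low counts (adjusted p = 0.105), with a mean CPM of at least 1 (adjusted p = 0.0745), with L and S copies summed (adjusted p = 0.0814) and, tested after the lists were called, without the 2 slc1a3 copies shared with the neural progenitor list (adjusted p = 0.141).

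Immediate early genes, which neurons and other cells induce on stimulation, were lower as a group. Of 68 gene models, egr1.L fell and 67 did not pass, and 4 fell adjusted over the list alone: both egr1 copies, gadd45g.S (-0.63) and klf2.S (-1.33). The median was -0.10 (camera adjusted p = 7.8e-05; adjusted p = 0.409 with an estimated correlation). The egr1.S copy was at -0.97 (adjusted p = 0.196), fos.L at -1.55 (adjusted p = 0.504) and fos.S at -1.41 (adjusted p = 0.743). The fos copies varied widely between the control libraries, at 13.4 and 6.51 CPM for fos.L. The junb.L (-0.52), junb.S (-0.29), nr4a1.L (-0.39), nr4a1.S (-0.42), jun.L (-0.24) and fosb.L (0.15) copies did not pass. Nor did jun.S (-0.08) and bdnf.S (-0.05), whose sign flips when libraries are scaled by their totals only. The npas4 and arc copies had at most 2 counts in any library and were not tested. FGF and MAPK feedback genes had a median of -0.13 over 44 gene models. This list shares egr1, fos, dusp1, dusp4, dusp5 and ier2 with the immediate early genes and was not tested without them. There egr1.L fell, 43 did not pass, and both egr1 copies and fgfbp1.L (-0.71) fell adjusted over the list alone (camera adjusted p = 0.000444; adjusted p = 0.409 with an estimated correlation).

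Receptor subunits that picrotoxin acts on were scarcely detected in these explants. The GABA-A subunit copies gabra2.L, gabra2.S and gabra5.S had enough counts to test, but at most 21 counts in a library. They had log2 fold changes of -0.27 ± 0.56, -0.08 ± 0.42 and 0.20 ± 0.53 (SE), with gabra2.S flipping sign under scaling by totals. With these standard errors, small or moderate changes in them, and some large ones, would not have passed. The list of GABA-A and glycine receptor subunits, 9 gene models with glra2.L at -1.28, was not called (camera adjusted p = 0.0763), with 0 genes passing over all genes or adjusted over the list alone. It was called lower with library totals only (adjusted p = 0.00499) and without picrotoxin replicate 1 (adjusted p = 0.0210). The list of GABA and glycine synthesis, transport and chloride balance, 25 gene models, was not called either (camera adjusted p = 0.139), but was called lower without picrotoxin replicate 1 (adjusted p = 0.0482).

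Circadian clock genes were higher. Of 21 gene models, nr1d1.L rose, 20 did not pass, and 4 rose adjusted over the list alone, the others being per2.L (0.44), cry1.L (0.46) and dbp.L (0.32). The median was 0.38 (camera adjusted p = 4.4e-07; adjusted p = 0.409 with an estimated correlation). Their mean log2 level relative to all libraries was -0.14 and -0.19 in the control libraries and 0.21 and 0.13 in the picrotoxin libraries.

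Extracellular matrix and collagen genes were higher, with a median of 0.09 over 95 gene models (camera adjusted p = 4.0e-05; adjusted p = 0.422 with an estimated correlation). The fibrillar collagen genes col1a1.S (0.55), col3a1.S (0.53) and col5a2.S (0.60) and the collagen VI genes col6a1.S (0.79) and col6a2.S (0.68) rose, 90 members did not pass, and 11 rose and 1 fell adjusted over the list alone. All 5 called copies, and krt12.5.S, lie on chromosome 9_10S, which carried 5.39% of the genes tested but 11 of the 22 higher calls (Fisher's exact test, two-sided p = 4.4e-09, chosen after the calls were seen). The median gene of 9_10S was at log2 -0.14 in control replicate 2 against the other libraries (865 genes). Genes of 9_10S thus moved together, while Fisher's test treats genes as independent, so its p does not measure the spread between pools. With the running chromosome medians of each library removed, krt12.5.S (0.66 ± 0.10, adjusted p = 0.0119), col6a1.S (0.72 ± 0.10, adjusted p = 0.00763) and col6a2.S (0.62 ± 0.10, adjusted p = 0.0217) kept their calls. The copies col5a2.S (0.55 ± 0.10, adjusted p = 0.0588), col3a1.S (0.48 ± 0.10, adjusted p = 0.117) and col1a1.S (0.42 ± 0.09, adjusted p = 0.120) did not. The L copies, added after the values were seen, did not pass over all genes, with col1a1.L at 0.66, col3a1.L at 0.43, col6a1.L at 0.34, col6a2.L at 0.33, col5a2.L at 0.11 and krt12.5.L at 0.12. Of these col3a1.L, col6a1.L and col6a2.L rose adjusted over the list alone. Without picrotoxin replicate 2, col1a1.L was at 0.97 and col3a1.L at 0.62. Leaving out each library, values ran from 0.47 to 0.63 for col1a1.S, 0.44 to 0.63 for col3a1.S and 0.52 to 0.69 for col5a2.S. Of the 5 called collagen copies, only col6a1.S kept its call in all of these fits. The mean log2 level of the list, relative to all libraries, was -0.02 and -0.06 in control replicates 1 and 2. It was 0.07 and 0.01 in picrotoxin replicates 1 and 2.

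**Figure D2:**
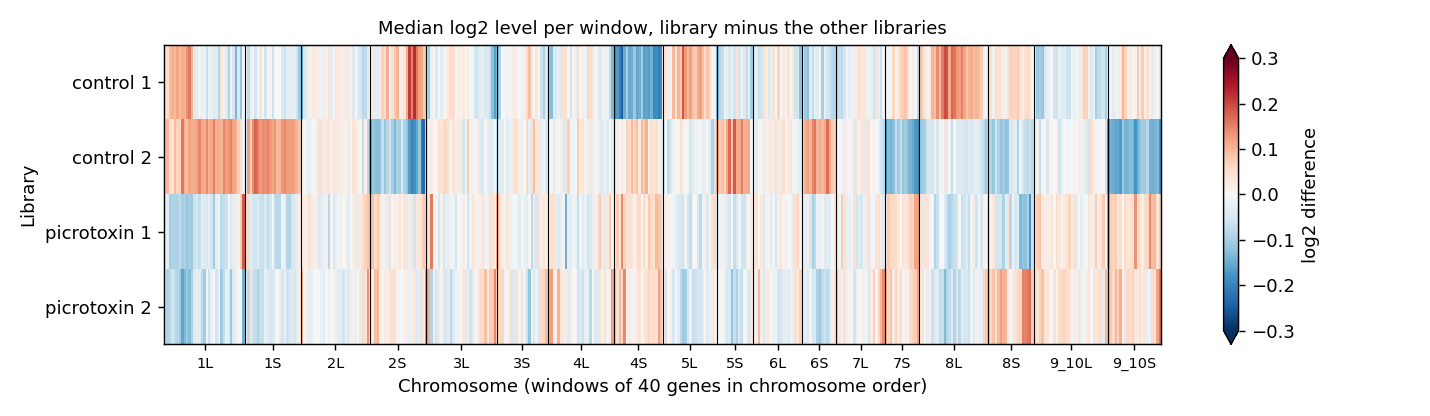
Median log2 level of windows of 40 genes in chromosome order (x axis) in each of the 4 libraries (y axis), against the mean of the other libraries; red is higher and blue lower, and colours saturate at the ends of the scale. Whole chromosomes stand apart in the control libraries, with 4S at -0.16 in control replicate 1 and 9_10S at -0.14 in control replicate 2.

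**Figure D3:**
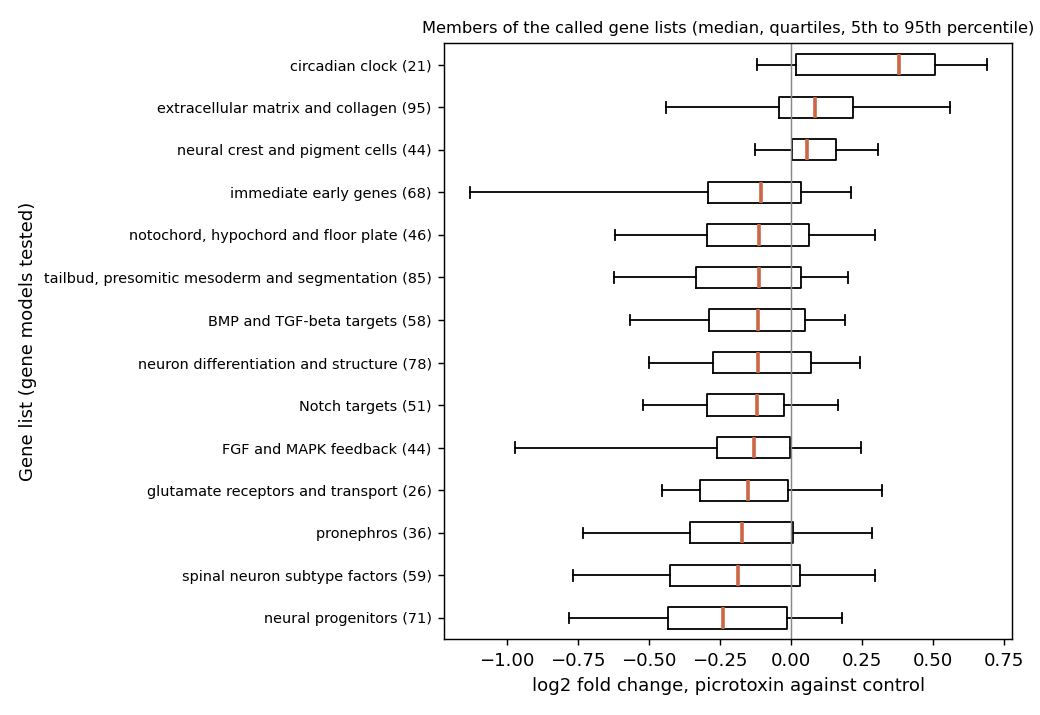
Log2 fold changes, picrotoxin against control, of the members of the 14 called gene lists, with the number of gene models tested in brackets. Boxes show the median and quartiles and whiskers the 5th to 95th percentile; medians run from -0.24 for neural progenitors to 0.38 for circadian clock genes.

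Lists of the mesoderm and other tissues were called with few or no single genes. Tailbud, presomitic mesoderm and segmentation genes had a median of -0.11 over 85 gene models. There dll1.S fell, over all genes and adjusted over the list alone, and 84 did not pass (camera adjusted p = 0.000608; adjusted p = 0.604 with an estimated correlation; adjusted p = 0.498 without picrotoxin replicate 1). BMP and TGF-beta targets had a median of -0.11 over 58, with 0 genes passing either way and ski.S at 0.48 (camera adjusted p = 0.00238; adjusted p = 0.484 with an estimated correlation; adjusted p = 0.141 without picrotoxin replicate 1). Pronephros genes had a median of -0.17 over 36, with 0 past the threshold over all genes. The transporter genes slc5a8.1.L (-0.50) and slc5a9.L (-1.24) fell adjusted over the list alone (camera adjusted p = 0.00378; adjusted p = 0.422 with an estimated correlation; adjusted p = 0.103 without control replicate 2). Notochord, hypochord and floor plate genes had a median of -0.11 over 46, with 0 passing either way and emilin3.S at -0.69 (camera adjusted p = 0.0328; adjusted p = 0.573 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.762) or picrotoxin replicate 1 (adjusted p = 0.141). Neural crest and pigment cell genes were higher, with a median of 0.06 over 44, 0 past the threshold over all genes and the melanin synthesis gene dct.L (0.52) rising adjusted over the list alone (camera adjusted p = 0.0231; adjusted p = 0.422 with an estimated correlation). The call was lost without control replicate 1 (adjusted p = 0.126) or picrotoxin replicate 1 (adjusted p = 0.108). The pigment gene pmel.L was at 0.28.

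Retinoic acid targets, 48 gene models, were not called as a list (camera adjusted p = 0.115), but 2 members fell, crabp2.L and cyp26c1.L, which encodes a retinoic acid degrading enzyme. The cyp26c1.L copy fell from 3.59 ± 1.06 to 0.39 ± 0.20 CPM (log2 fold change -3.25 ± 0.39, adjusted p = 0.000125), while cyp26c1.S stood at 19.2 ± 0.22 CPM in control and 27.4 ± 0.43 in picrotoxin libraries (0.51 ± 0.11, adjusted p = 0.0598). Adjusted over the list alone, 3 fell, the third being cdx4.L (-0.45), and 2 rose, among them cyp26c1.S. How well the counting tells reads of the copies apart is not known, so the level of each copy is uncertain.

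The remaining lists were not called. Their camera adjusted p was 0.0785 for sterol and lipid synthesis, 0.0851 for posterior Hox genes, 0.0862 for neuropeptides and monoamine genes, 0.0862 for histone genes, 0.113 for multiciliated cells and ionocytes. It was 0.115 for ER stress and the integrated stress response, and 0.117 for both epidermis, where krt12.5.S rose, and skeletal muscle. It was 0.141 for the cell cycle, 0.218 for Wnt targets, 0.218 for endoderm and yolk-rich gut, 0.218 for p53 targets and apoptosis, where ccng2.S was at -0.59. It was 0.296 for heat shock, where dnaja1.L was at -0.48, 0.353 for cholinergic genes and 0.353 for myeloid cells and inflammation. It was 0.371 for xenobiotic metabolism, 0.382 for ribosomal protein genes, 0.455 for calcium handling, 0.525 for voltage-gated ion channels, 0.594 for Hedgehog targets. For the others it was 0.602 for hypoxia and glycolysis, 0.602 for anterior Hox genes and hindbrain, 0.643 for limb, lateral plate and heart, and 0.783 for blood and endothelium. Of the 27 lists not called, 15 were called in at least 1 alternative. With running chromosome medians removed these were the cell cycle (adjusted p = 0.0254), histone genes (adjusted p = 0.0292) and multiciliated cells (adjusted p = 0.0372), all lower, and retinoic acid targets (lower, adjusted p = 0.0316). Myeloid genes were called lower without picrotoxin replicate 1 (adjusted p = 1.6e-08) and higher without picrotoxin replicate 2 (adjusted p = 0.00442).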

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

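The settings that removed ribosomal RNA gene models, set legacy = FALSE or removed chromosome medians were chosen after the data were seen. Over all alternatives, 1159 values of the named genes kept the direction of the fit of all libraries and 10 turned, and all 224 values of the called lists kept theirs. Apart from genes fixed in advance and L copies added later, these genes and lists were chosen by their values in that fit. The alternatives refit the same libraries, so the kept directions largely follow from the choice and are no independent support. The count of 47 genes (22 higher, 25 lower) was 22 (11 and 11) with library totals only, which shifts the median gene by log2 0.11. It was 22 (14 and 8) with DESeq2, 14 (8 and 6) with limma-voom, 14 (8 and 6) with robust = FALSE, 189 (71 and 118) with no filter on low counts. It was 24 (12 and 12) with legacy = FALSE, and 16 (8 and 8) with running chromosome medians removed. All 47 were among the calls with no filter, 15 among those with each of totals and DESeq2, and 14 among those with each of limma-voom and robust = FALSE. All 16 of the running-median calls were among the 47. With medians per chromosome removed, 32 genes were called (13 higher, 19 lower), 26 of them among the 47. Leaving out each library gave 15 to 158 genes, 8 to 62 higher and 7 to 96 lower. With robust = FALSE and with running medians removed, the median prior degrees of freedom of the dispersion step (estimateDisp) were 12.1 and 13.3, against 22.2. The quasi-likelihood test uses a prior of its own, which was not recorded, so these values cannot explain the lower counts. For egr1.L the fold moved little, from -1.13 ± 0.19 to -1.08 ± 0.19 (adjusted p = 0.0734) with running medians removed. The cause of the lower counts was not tested. The 14 called lists fell to 0 with an estimated correlation and to 1 with fry. The estimated correlation was -0.013 for neural progenitors, -0.012 for clock genes and -0.017 for Notch genes, below the preset 0.01. Their call was lost as camera then uses only 2 residual degrees of freedom. The estimate was 0.19 for neuron differentiation, 0.19 for glutamate and 0.16 for tailbud genes, whose preset p is then too small. The called lists were 18 with library totals only and with either removal of chromosome medians, all 14 among them. Leaving out each library gave 12 to 17 lists, of which 10 to 12 were among the 14; the lone library of a group was assumed to vary like those of the other group. Directions turned with library totals only for jun.S (0.0368), bdnf.S (0.0614) and gabra2.S (0.0310). Leaving out each library, values ran from -0.260 to 0.115 for jun.S, from -0.212 to 0.126 for bdnf.S, from -0.290 to 0.144 for gabra2.S, from -0.169 to 0.760 for gabra5.S and from -0.615 to 0.0692 for gabra2.L. The direction of cyp26c1.L turned (0.289) where L and S copies were summed, since cyp26c1.S then dominates. Of these genes only cyp26c1.L passed in the fit of all libraries. The labels do not say what a shared replicate number means. Deviations of same-numbered libraries from the group means correlated at -0.02 over genes. With 2 libraries per group this cannot exclude a shared clutch. The replicate block gave 41 genes, 16 higher and 25 lower, 31 of them shared with the 47. The planned legacy = TRUE fit is the one used throughout, the default of the installed version. The other splits of the 4 libraries into pairs gave 9 and 6 genes, and 3 splits are too few for a share under 0.05.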

Other observations

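The tests below were chosen after the results they bear on were seen, apart from the leave-one-out test of the neural progenitor list.

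Genes of whole chromosomes lay higher or lower together in single libraries, and most of all in the control libraries. In control replicate 1 the median gene of 4S was at log2 -0.16 against the other libraries (95% interval -0.18 to -0.15, 763 genes), lower in 20 of 20 windows of 40 genes, and that of 8L at 0.10. In control replicate 2 the medians were -0.14 for 9_10S, -0.13 for 7S, -0.12 for 2S and -0.08 for 8S, and 0.12 for 1S, 0.11 for 5S, 0.11 for 6S and 0.10 for 1L. Among picrotoxin libraries the farthest was 8S, at 0.09 in replicate 2. At an unadjusted p under 0.01, 45 genes of 9_10S were higher and 8 lower with picrotoxin, against 7 and 64 on 1L, and with running chromosome medians removed these became 27 and 18, and 16 and 29.

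Chance scatter was argued against by 36 of 72 medians lying beyond 0.0294, the farthest of 1000 shuffles. Each library was set against the mean of the others, so 1 library that stands apart also moves the rest. For 4S, control replicate 2 and both picrotoxin libraries were each at 0.05 and are counted too. The 36 therefore overstate the number of separate offsets. A gene property or tissue makeup that homeologs share was argued against for chromosome 4 in control replicate 1 by the S minus L difference within 480 pairs, at a median of -0.138 (95% interval -0.156 to -0.120). In control replicate 2 this difference was -0.149, 0.140, 0.120, -0.144 and -0.123 for chromosomes 2, 5, 6, 7 and 9_10. For chromosome 1 it was only 0.0198 there (95% interval 0.00654 to 0.0334, 567 pairs), since 1L and 1S moved together, and a shared property stays open for that pair. Other copy numbers of chromosomes in some pooled embryos were not tested, since DNA was not analysed here. With 3 embryos in a pool, 1 embryo with 1 or 3 copies would move a chromosome by -0.26 or 0.22, more than was measured. These values assume equal RNA from each embryo and expression in proportion to copies, neither of which is known, so they do not decide. Part of 1L in control replicate 1 moved without the rest. A difference between clutches also stays open, and no biological explanation from the design was tested.

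The lower neural lists were weighed against these offsets. With running chromosome medians removed, the neural progenitor list kept its camera call (adjusted p = 9.1e-10), which argues against the offsets as the whole cause, and across its alternatives the adjusted p ran from 8.6e-10 to 0.409, the last with an estimated correlation. Dependence on 1 library was argued against by the largest adjusted p of the 4 leave-one-out fits, 7.2e-06 with camera's preset correlation, where the lone library of a group was assumed to vary like those of the other group. A smaller share of neural tissue in the picrotoxin pools, from cutting or yolk removal, could not be told apart from a change within the cells: the progenitor median minus the neuron median was -0.124, with a 95% bootstrap interval of -0.274 to 0.0201, too wide to decide. An effect of picrotoxin also stays open.

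For cyp26c1, reads assigned to the other homeolog could make the L copy fall and the S copy gain. The S copy gained 8.20 CPM, more than the 3.59 CPM the L copy had in control libraries. The summed copies moved by log2 0.289 ± 0.106 (SE; unadjusted p = 0.0122, adjusted p = 0.449 over all genes in that edgeR fit). That argues against reassignment as the whole account, though not against a part of it, and the summed change did not pass over all genes. The S copy lies on 7S, whose median gene was at log2 0.09 with picrotoxin against control. The summed copies were not tested with that offset removed. The spread between the libraries of the summed copies (SE 0.615 CPM) was smaller than counting alone gives (1.12 CPM), so the moderated fit was used.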
